A study of Mus musculus with 12 samples.

How the data were processed

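Gene expression was measured on 12 Affymetrix mouse arrays in 4 groups of 3. Per the labels' protocols, cells of the mouse neuroblastoma line TT9423 formed spheres on agar and bone marrow-derived macrophages from C57BL/6 mice were added to them. In-sphere macrophages carry the label CD11b-positive, after enzymatic digestion of the spheres and selection on CD11b magnetic columns, and the other macrophages stayed outside the spheres of those cultures. The protocol text is shared by all samples, and whether cells from outside the spheres were digested or selected in the same way is not given in the sources used here. Collection was at 24 h or 48 h, per the titles and the time label, although the protocol text on every sample, those of 48 h included, describes a co-culture of 24 h. Each replicate was an independent experiment with cells pooled over several wells, per the series' design text. Biotin-labelled cRNA was made from total RNA with a 3' IVT kit, per the labels' protocols.

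The deposited values are log2 expression per probe set, made by the authors with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA corrects the background, quantile-normalises the arrays together and summarises the probes of a set, which compresses differences of dim probe sets and removes any difference in total RNA per cell. The log base is taken as 2 from the range of the values. Scanner files were not used here. The table held 45141 probe sets with 0 missing values, and array medians ran from 3.03 to 3.17 on the log2 scale. For arrays, precision is limited by their number.

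Gene names came from the platform annotation. Exactly 1 symbol was given for 28898 probe sets and several for 551, while 15692 were not named, 104 of the table's probe sets being array controls. Symbols were checked through the gene identifiers of the mouse RefSeq table of the GRCm38 assembly, which matched 28689 single-gene probe sets and changed 0 symbols, and no coordinates were used. For each of 17097 genes the probe set with the highest mean over all arrays was kept. A gene was tested if that probe set exceeded 2.77, the 40th percentile of all values, in at least 3 arrays, which left 12488 genes.

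All arrays entered a single group-means model in limma 3.58.1 (R 4.3.3), with lmFit, contrasts.fit and eBayes, 8 residual degrees of freedom and 4.09 prior degrees of freedom. The 6 contrasts were in-sphere against outside at each time, the mean of those differences, 48 h against 24 h in each compartment, and the change of the in-sphere difference between times. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and calls with an absolute log2 difference of at least 1 were counted beside them. Errors of differences are standard errors of this fit.

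Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists within a comparison. The lists covered macrophage identity, alternative and classical activation, NF-kB feedback and early cytokines, interferon-stimulated genes, hypoxia response, glycolysis, tumour-associated macrophage effectors, MHC class II presentation, cholesterol synthesis, LXR and lipid handling, DNA replication, mitosis, unfolded protein and amino acid response, immediate-early and heat-shock genes, NRF2 and oxidative stress, lysosome, engulfment of apoptotic cells, complement, chemokine receptors and trafficking, oxidative phosphorylation, and apoptosis regulators. Markers of other cells covered neuroblastoma and neural, fibroblast and stromal, endothelial, granulocyte, dendritic, lymphocyte, and mast cell and basophil genes. Of 552 distinct list genes, 489 had a single-gene probe set and 456 were tested. Groups, comparisons, lists, the filter and the naming rule were chosen before the data were examined.

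Genes named in the text follow that rule. For the in-sphere comparison at each time it takes the 8 largest differences per direction among called genes whose arrays do not overlap between the groups, passing over uncharacterised gene models, and 5 per direction for the other contrasts. It adds up to 4 called members per list (or up to 2 as values where none was called) and a fixed set of macrophage and marker genes. Of that set, Spp1 was not analysed here.

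The replicate numbers come from the labels. Deviations from the group means were correlated over genes between arrays with the same number to check whether the numbers pair the samples. Outside arrays at 24 h and 48 h gave 0.471, 0.473 and 0.419 for the 3 numbers, each above 0.1. Values for in-sphere against outside arrays were 0.0215, 0.120 and 0.0813 at 24 h and 0.117, 0.0417 and 0.112 at 48 h, and in-sphere arrays between times gave 0.116, 0.140 and 0.0247. In-sphere arrays at 24 h against outside arrays at 48 h gave 0.123, 0.219 and 0.0998. Outside arrays at 24 h against in-sphere arrays at 48 h gave 0.173, 0.0633 and 0.158. The numbers were taken as pairing the samples, which rests on the outside arrays, since not every value of the other pairs of groups exceeded 0.1. The main fit leaves this pairing out, so its counts and p-values are unpaired. A fit with the replicate block was run as an alternative.

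Other alternatives were a random block within time, the mean of a gene's probe sets, leaving out probe sets prone to cross-hybridisation, no filter and a filter at the 60th percentile, median centring, cyclic loess, a trended robust eBayes, array weights, a fit to the compared groups alone, limma's treat against 0.5, and leaving out each array in turn. For lists they were camera with an estimated correlation and fry, whose p tests whether a list moves on balance one way and compares it with no other genes. A gene's range of adjusted p over all alternatives includes treat, which asks whether the difference exceeds 0.5. Its upper end can come from that stricter question. The pipeline was tested on simulated data with 200 changed genes among 12488. For the in-sphere difference at 24 h it recovered 14.9% of genes changed by 0.500, 74.6% of those changed by 1 and 97.0% of those changed by 2 on the log2 scale. For the change of that difference between times the shares were 1.49%, 41.8% and 90.9%. The simulated errors were independent, and far fewer genes were changed than limma called for the in-sphere comparisons. These shares therefore need not hold for the data.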

Results

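Macrophages that had entered tumour spheres were compared with macrophages of the same cultures that had not, at 24 h and 48 h, with n = 3 independent experiments per group. TT9423 is a mouse neuroblastoma line, and its spheres with added bone marrow-derived macrophages served as a culture model of tumour-associated macrophages. The times are those of the titles and the time label, while the protocol text shared by all samples describes a co-culture of 24 h, so what 48 h means rests on those labels alone. The first principal component held 66.9% of the variance and placed all 6 in-sphere arrays on one side. Correlations between an in-sphere and an outside array ran from 0.950 to 0.976. The most similar pair of arrays still differed by a median of 0.143 on the log2 scale, so no array was a copy of another. Replicate 3 in spheres at 48 h stood apart, with a mean log2 value of 4.06 against 4.22 and 4.22 in the other replicates and the lowest array weight, 0.235.

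At 24 h, the largest fitted differences toward the in-sphere cells were those of Crabp1, a retinoic acid-binding protein, at a log2 difference of 7.60 ± 0.62 (SE, n = 3 against 3), and the Wnt antagonist Dkk2 at 5.06 ± 0.22. They were followed by the alarmin Il33 (4.87 ± 0.36), Nrn1 (4.81 ± 0.28), the cholesterol hydroxylase Ch25h (4.43 ± 0.22), the Notch-family ligand Dlk1 (4.38 ± 0.23), the arginine-degrading enzyme Arg1 (4.22 ± 0.93) and the chemokine Ccl12 (4.17 ± 0.57). Lower in spheres were the bone matrix protein gene Ibsp (-4.48 ± 0.28), the platelet and myeloid lectin receptor Clec1b (-4.26 ± 0.47), Ipcef1 (-3.88 ± 0.39), Irx3 (-3.75 ± 0.27), Ceacam10 (-3.67 ± 0.54), the alpha-globin gene Hba-a1 (-3.67 ± 0.47), the cadherin Cdh11 (-3.36 ± 0.28) and Ankrd22 (-3.31 ± 0.31). In all, limma called 3669 of 12488 genes, 1975 higher and 1694 lower, of which 781 and 529 differed by at least 1 on the log2 scale. Among the 16 genes named here the adjusted p ran from 2.77e-07 for Dkk2 to 0.00470 for Arg1, whose values outside spheres were widely spread (8.41 ± 1.63, mean ± SD, against 12.63 ± 0.27 in spheres). Dkk2 outside and Ibsp in spheres exceeded the filter level of 2.77 on 0 of 3 arrays, so their differences have only bounds, at least 4.41 and 3.69 in size against that level. Il33 outside exceeded it on 1 of 3 arrays, and Crabp1 outside and Clec1b and Cdh11 in spheres on 2, so that these genes have no settled order by size. The 3' minus 5' log2 signal of the beta-actin control, which rises with RNA degradation, was 0.481 ± 0.127 in spheres and 0.285 ± 0.0535 outside (mean ± SD) at 24 h without overlap (exact permutation p = 0.10, the smallest that 3 against 3 arrays allow). That of the GAPDH control was 0.157 ± 0.275 in spheres and 0.0522 ± 0.108 outside (mean ± SD), with overlap (exact permutation p = 0.70).

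**Figure D1:**
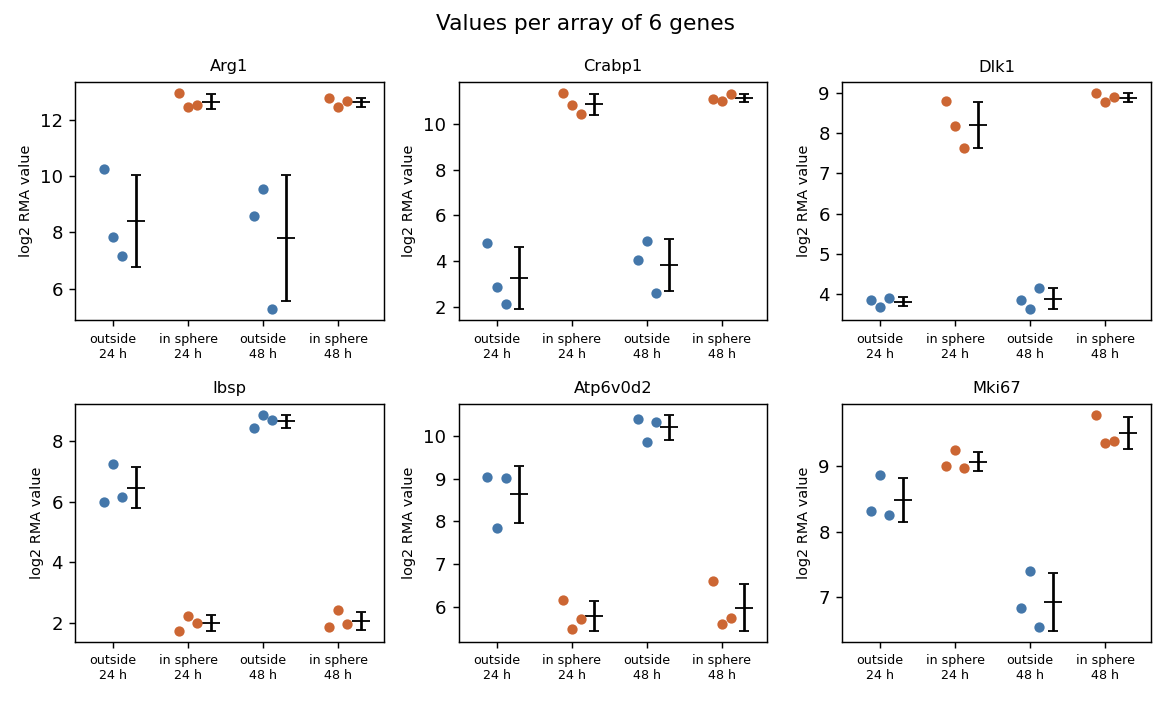
Log2 RMA values of 6 genes per array (points) in the 4 groups, with the mean and SD of the 3 arrays of a group beside them. Arg1, Crabp1 and Dlk1 lie higher and Ibsp and Atp6v0d2 lower in every in-sphere array than in every outside array of the same time, and Mki67 outside spheres averages 8.48 at 24 h and 6.92 at 48 h.

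Genes of oxygen deprivation and sugar use were higher in spheres at 24 h. Medians of a list are those of its members' log2 differences, and its counts are of higher and then lower members. Of 23 tested hypoxia response genes 20 were higher and 0 lower (21 and 0 adjusted over the list alone). The median was 1.80 (camera adjusted p = 3.81e-14, adjusted p = 0.198 with an estimated correlation). They included the collagen-modifying enzymes Plod2 (3.36 ± 0.23) and P4ha2 (2.54 ± 0.23) and the carbonic anhydrase Car9 (2.72 ± 0.23). Among 14 glycolysis genes 12 were higher and 0 lower (13 and 0 adjusted over the list alone). The median was 0.85 (camera adjusted p = 2.81e-08, adjusted p = 0.198 with an estimated correlation). Among them were Aldoc (2.46 ± 0.33) and Pfkp (1.73 ± 0.15). The angiogenic factor Vegfa was higher at 0.50 ± 0.14, adjusted p = 0.0189, a call lost without outside replicate 2 (adjusted p = 0.0824, from 3.43e-04 to 1.00 over all alternatives). Limma called 0 of 19 oxidative phosphorylation genes, with 1 higher and 2 lower at an unadjusted p under 0.05 (0 and 0 adjusted over the list alone, camera adjusted p = 0.978). The largest differences there were those of Ndufv1 at 0.30 ± 0.13 and Sdhb at -0.25 ± 0.096.

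Cell division genes were also higher at 24 h. Of 23 DNA replication genes 20 were higher and 1 lower (20 and 1 adjusted over the list alone). The median was 1.35 (camera adjusted p = 5.87e-12, adjusted p = 0.198 with an estimated correlation). The replicative helicase subunits Mcm5 (1.95 ± 0.27) and Mcm7 (1.70 ± 0.21) and the thymidine kinase Tk1 (1.88 ± 0.23) were among them. For 23 mitosis genes 16 were higher and 0 lower (21 and 0 adjusted over the list alone). The median was 1.04 (camera adjusted p = 4.49e-08, adjusted p = 0.519 with an estimated correlation). Among them were the spindle checkpoint kinases Ttk (1.98 ± 0.33) and Bub1 (1.78 ± 0.30). The proliferation marker Mki67 differed by 0.59 ± 0.23, adjusted p = 0.0674, which passed with the replicate block (adjusted p = 0.0340, from 0.0160 to 1.00 over all alternatives).

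Cholesterol synthesis and stress response genes were higher too. Among 19 cholesterol synthesis genes 11 were higher and 0 lower (13 and 0 adjusted over the list alone). The median was 0.63 (camera adjusted p = 3.89e-05, adjusted p = 0.378 with an estimated correlation). Among them were Fdps (1.58 ± 0.19) and Sqle (1.53 ± 0.22). The unfolded protein and amino acid response had 21 tested members, of which 11 were higher and 1 lower (13 and 2 adjusted over the list alone). The median was 0.43 (camera adjusted p = 3.95e-04, adjusted p = 0.206 with an estimated correlation). Its leading members were the transsulfuration enzyme Cth (3.32 ± 0.25), Vldlr (2.84 ± 0.26) and the serine synthesis enzymes Psat1 (2.20 ± 0.21) and Phgdh (1.81 ± 0.15). Cth outside exceeded the filter level on 0 of 3 arrays, its difference being at least 2.69 against that level, and Vldlr outside on 1.

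Lipid, antioxidant and lysosomal genes were lower in spheres at 24 h. Of 16 LXR and lipid handling genes 2 were higher and 14 lower (2 and 14 adjusted over the list alone). The median was -0.99 (camera adjusted p = 7.14e-06, adjusted p = 0.198 with an estimated correlation). The fatty acid-binding protein Fabp4 (-1.79 ± 0.24), the nuclear receptor Pparg (-1.76 ± 0.19) and the acid lipase Lipa (-1.45 ± 0.13) were lower, against the desaturase Scd1 at 2.70 ± 0.27. Of 16 NRF2 and oxidative stress genes 0 were higher and 13 lower (1 and 14 adjusted over the list alone). The median was -0.83 (camera adjusted p = 7.28e-08, adjusted p = 0.198 with an estimated correlation). Among them were Nqo1 at -1.96 ± 0.35 and Osgin1 at -1.64 ± 0.17. Of 19 lysosome genes 0 were higher and 14 lower (0 and 15 adjusted over the list alone). The median was -0.59 (camera adjusted p = 7.28e-08, adjusted p = 0.206 with an estimated correlation). Among them were the proton pump subunit Atp6v0d2 at -2.85 ± 0.34 and Gpnmb at -1.21 ± 0.17. In all, 7 lists were called higher and 5 lower at 24 h, of which 0 held with an estimated correlation, where the smallest adjusted p was 0.198.

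Macrophage activation genes split at 24 h. Of 16 alternative activation genes 5 were higher and 5 lower (5 and 5 adjusted over the list alone, camera adjusted p = 0.978). They included Arg1 and fibronectin Fn1 (1.88 ± 0.17) higher and the lectin Clec7a (-2.14 ± 0.12) and Retnla (-1.48 ± 0.21) lower. The mannose receptor Mrc1 was higher at 1.08 ± 0.28, adjusted p = 0.0111. Of 15 classical activation genes 3 were higher and 2 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.532), the chemokine Cxcl11 differing by 2.31 ± 0.31. Retnla in spheres exceeded the filter level on 0 of 3 arrays, its difference being at least 0.91 in size. Tnf, averaging 10.46 ± 0.040 outside (mean ± SD), did not pass (-0.29 ± 0.14, adjusted p = 0.154). The nitric oxide synthase Nos2 averaged 2.89 in spheres and 2.82 outside, close to the filter level, so a difference was not detectable at this signal (0.068 ± 0.17, adjusted p = 0.813). The cytokine Il10 was lower at -0.72 ± 0.24, adjusted p = 0.0402, but its call was lost when any of 5 of the 6 arrays was left out. The adjusted p was then 0.164 without in-sphere replicate 1, 0.0511 without in-sphere replicate 2, and 0.0770, 0.0600 and 0.129 without outside replicates 1, 2 and 3, and it ran from 0.00419 to 0.990 over all alternatives. The checkpoint ligand Cd274 (-0.063 ± 0.16, adjusted p = 0.827) and the integrin Itgam, which encodes CD11b (0.15 ± 0.25, adjusted p = 0.729), did not pass.

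Signalling and antigen presentation lists were mixed at 24 h. Of 19 NF-kB feedback and early cytokine genes 5 were higher and 1 lower (5 and 1 adjusted over the list alone), led by the monocyte chemokines Ccl7 (1.78 ± 0.25) and Ccl2 (1.46 ± 0.16). The list did not pass (camera adjusted p = 0.0553) but did with the replicate block (adjusted p = 0.0348 with the block, from 0.0205 to 0.720 over all alternatives). Limma called 0 of 21 interferon-stimulated genes, with 0 higher and 0 lower at an unadjusted p under 0.05 (0 and 0 adjusted over the list alone, camera adjusted p = 0.660). Gbp2 differed by 0.94 ± 0.44. Tumour-associated macrophage effectors had 7 higher and 8 lower of 23 (7 and 8 adjusted over the list alone, camera adjusted p = 0.978). The protease genes Plau (2.19 ± 0.19) and Mmp2 (1.94 ± 0.27) and the matrix protein Tgfbi (1.91 ± 0.18) were higher. Of 14 MHC class II presentation genes 2 were higher and 2 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.660). The class II chains H2-Eb1 (-1.67 ± 0.37) and H2-Aa (-1.39 ± 0.23) were lower and the loading factor H2-DMa (1.12 ± 0.24) was higher.

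Trafficking, stress and survival lists were also mixed. Among 11 chemokine receptor and trafficking genes 4 were higher and 3 lower (4 and 3 adjusted over the list alone, camera adjusted p = 0.874), with the fractalkine receptor Cx3cr1 at 2.50 ± 0.21. Immediate-early and heat-shock genes, which respond to tissue dissociation, had 5 higher and 8 lower of 20 (6 and 10 adjusted over the list alone, camera adjusted p = 0.422). Socs3 (1.67 ± 0.15) and Hspa1b (1.36 ± 0.15) were higher and Jun (-1.52 ± 0.22) and Btg2 (-1.29 ± 0.17) were lower. Of 15 apoptosis regulators and p53 targets 3 were higher and 5 lower (3 and 5 adjusted over the list alone, camera adjusted p = 0.283), Trp53inp1 differing by -2.46 ± 0.23 and Bcl2 by 1.65 ± 0.19. Complement had 1 called member of 12 (1 and 0 adjusted over the list alone, camera adjusted p = 0.332), C1s1 at 2.12 ± 0.25.

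Markers of other cell types differed between the compartments at 24 h. No array of TT9423 cells alone was analysed here, so carried-over sphere cells could be examined only through these lists. RNA of such cells would enter every in-sphere difference, those of Crabp1, Dkk2, Dlk1 and of the lists above included. These differences alone therefore do not place the expression in macrophages. Whether cells from outside were digested or selected on CD11b in the same way is not given. Lower values in spheres, those of Hba-a1, Clec1b and the granulocyte markers included, therefore cannot be told apart from a difference in preparation. Of 15 fibroblast and stromal markers 8 were higher and 2 lower (10 and 2 adjusted over the list alone). The median was 1.25 (camera adjusted p = 0.00668, adjusted p = 0.570 with an estimated correlation). Among them were the collagen Col3a1 (2.64 ± 0.31), the proteoglycan Dcn (2.60 ± 0.55), Thy1 (2.36 ± 0.23) and Pdgfra (1.90 ± 0.35), which exceeded the filter level outside on 1 of 3 arrays. Of 20 neuroblastoma and neural markers 2 were higher and 0 lower (2 and 0 adjusted over the list alone, camera adjusted p = 0.660). These were the growth cone protein Gap43 (3.99 ± 0.30) and Ncam1 (0.99 ± 0.20), of whose 5 other probe sets 4 were not called. Of 13 granulocyte markers 0 were higher and 9 lower (0 and 9 adjusted over the list alone). The median was -1.04 (camera adjusted p = 0.00170, adjusted p = 0.570 with an estimated correlation). Among them were the granule proteins Camp (-2.17 ± 0.43) and Ltf (-1.95 ± 0.32) and the receptor Csf3r (-2.14 ± 0.30), all lower. Of 20 macrophage identity genes 1 was higher and 6 lower (1 and 6 adjusted over the list alone). The median was -0.34 (camera adjusted p = 0.0279, adjusted p = 0.522 with an estimated correlation). Among them were the transcription factor Cebpa (-1.47 ± 0.19) and the engulfment receptor Mertk (-0.91 ± 0.15) lower and Cd14 (0.54 ± 0.13) higher. The lower members numbered 10 without in-sphere replicate 3 and 3 without outside replicate 1.

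Other marker lists did not pass as lists at 24 h. Endothelial markers had 3 of 9 lower (0 and 3 adjusted over the list alone, camera adjusted p = 0.109), with Vwf at -2.06 ± 0.29. Lymphocyte markers had 2 of 9 lower (0 and 2 adjusted over the list alone, camera adjusted p = 0.660), and mast cell and basophil markers 3 of 5 (0 and 4 adjusted over the list alone, camera adjusted p = 0.102). The mast cell calls were those of Cpa3 (-1.92 ± 0.63), Gata1 (-0.45 ± 0.16) and Kit (-0.43 ± 0.14). Kit in spheres exceeded the filter level on 0 of 3 arrays, and Cpa3 and Gata1 on 2. The replicate block ended the call of Gata1 (adjusted p = 0.0670, from 0.0230 to 1.00 over all alternatives). All 3 mast cell calls were lost without in-sphere replicate 1 (adjusted p = 0.116, 0.0880 and 0.0669), outside replicate 2 (adjusted p = 0.138, 0.0739 and 0.0713) or outside replicate 3 (adjusted p = 0.133, 0.189 and 0.0569), each fit leaving 0 called members. Without in-sphere replicate 2 or 3, 1 member was called. Over all alternatives the adjusted p of these genes ran from 0.00315 to 1.00. Of the lymphocyte calls 1 was left without in-sphere replicate 1 or outside replicate 2 or 3. Of 7 dendritic cell markers 1 was higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.967). That was the actin bundler Fscn1 at 1.90 ± 0.30, where a probe set not used gave -0.11. Median, mean and test differed in sign at 24 h for alternative activation, tumour-associated macrophage effectors, dendritic cell markers, lymphocyte markers and chemokine receptors and trafficking.

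At 48 h, Crabp1 (7.29 ± 0.62), Ch25h (5.20 ± 0.22), Dkk2 (5.09 ± 0.22), Ccl12 (5.07 ± 0.57), Dlk1 (4.99 ± 0.23) and Arg1 (4.83 ± 0.93) again had the largest fitted differences toward the in-sphere cells, joined by the mechanical-stress gene Ankrd1 (5.27 ± 0.27) and the cell-cycle inhibitor Cdkn2a (4.66 ± 0.38). Lower were Ibsp (-6.59 ± 0.28) and Dmp1 (-5.81 ± 0.64), both known from bone matrix, the chitinase-like gene Chil1 (-4.25 ± 0.44), Atp6v0d2 (-4.23 ± 0.34), Ceacam10 (-4.22 ± 0.54), Olfm4 (-4.09 ± 0.31), Cdh11 (-4.01 ± 0.28) and the nutrient-sensing GTPase Rragd (-3.93 ± 0.25). The fit called 4685 genes, 1904 higher and 2781 lower, of which 826 and 805 differed by at least 1. Adjusted p for the 16 named genes ran from 7.63e-08 for Ibsp to 0.00150 for Arg1. The balance of directions depended on scaling, since cyclic loess gave 2597 higher and 2207 lower, and moved the median of all genes from -0.10 to 0.021. Leaving out in-sphere 24 h replicate 1 and 48 h replicate 3, chosen after seeing the data, gave 2241 higher and 2336 lower at 48 h and 3521 calls at 24 h. Dkk2 outside and Ibsp and Cdh11 in spheres exceeded the filter level on 0 of 3 arrays, so their differences are at least 4.58, 5.89 and 3.70 in size against that level. Ankrd1 outside exceeded it on 1 of 3 arrays, and Crabp1 outside and Dmp1 in spheres on 2, so that these genes have no settled order either. The beta-actin value was 0.405 ± 0.0114 in spheres and 0.386 ± 0.0134 outside (mean ± SD) at 48 h, with overlap (exact permutation p = 0.20), and the GAPDH value 0.124 ± 0.0196 in spheres and 0.0794 ± 0.0235 outside (mean ± SD), without overlap (exact permutation p = 0.10).

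Cell division genes were higher at 48 h as well. All 23 tested mitosis genes were higher (23 and 0 adjusted over the list alone). The median was 2.64 (camera adjusted p = 6.35e-21, adjusted p = 0.209 with an estimated correlation). The largest values were those of Bub1 (3.16 ± 0.30), Ube2c (3.02 ± 0.31) and Ccnb2 (2.88 ± 0.33). Of 23 genes of the DNA replication list 21 were higher and 0 lower (21 and 0 adjusted over the list alone). The median was 1.74 (camera adjusted p = 7.35e-17, adjusted p = 0.161 with an estimated correlation). Its members included Tk1 at 2.82 ± 0.23 and Mcm7 at 2.56 ± 0.21. Mki67 was higher at 2.59 ± 0.23, adjusted p = 5.89e-06.

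Metabolic and stress response lists were higher too. Of 23 genes of the hypoxia response list 20 were higher and 0 lower (21 and 0 adjusted over the list alone). The median was 1.62 (camera adjusted p = 1.15e-15, adjusted p = 0.161 with an estimated correlation). Its members included the vasoactive peptide Adm at 2.89 ± 0.35 and Vegfa at 1.01 ± 0.14, adjusted p = 1.90e-04. Of 14 genes of the glycolysis list 12 were higher and 0 lower (12 and 0 adjusted over the list alone). The median was 0.86 (camera adjusted p = 1.72e-07, adjusted p = 0.209 with an estimated correlation). Its members included Aldoc at 1.97 ± 0.33. Of 19 genes of the cholesterol synthesis list 9 were higher and 0 lower (10 and 0 adjusted over the list alone). The median was 0.54 (camera adjusted p = 4.42e-05, adjusted p = 0.257 with an estimated correlation). Its members included Fdps at 2.02 ± 0.19 and Idi1 at 1.60 ± 0.14. Of 21 genes of the unfolded protein and amino acid response list 12 were higher and 3 lower (12 and 3 adjusted over the list alone). The median was 0.41 (camera adjusted p = 0.00102, adjusted p = 0.209 with an estimated correlation). Its members included Cth at 2.96 ± 0.25 and Psat1 at 2.37 ± 0.21, Cth outside exceeding the filter level on 0 of 3 arrays (at least 2.62 against it).

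Inflammatory lists were higher at 48 h. Of 19 genes of the NF-kB feedback and early cytokines list 9 were higher and 0 lower (9 and 0 adjusted over the list alone). The median was 0.48 (camera adjusted p = 5.66e-05, adjusted p = 0.351 with an estimated correlation). Its members included Ccl7 at 2.64 ± 0.25 and Ccl2 at 2.26 ± 0.16. Of 15 genes of the classical activation list 8 were higher and 1 lower (9 and 1 adjusted over the list alone). The median was 0.83 (camera adjusted p = 0.00375, adjusted p = 0.220 with an estimated correlation). Its members included Cxcl10 (2.69 ± 0.28) and the interleukin Il6 (1.75 ± 0.37), while Nos2, at 2.78 in spheres and 2.62 outside, was again too close to the filter level for a difference to be detectable (0.16 ± 0.17, adjusted p = 0.489). Immediate-early and heat-shock genes had 7 higher and 1 lower of 20 (7 and 2 adjusted over the list alone, camera adjusted p = 0.0376, adjusted p = 0.209 with an estimated correlation), with Hspa1b at 2.17 ± 0.15. That list call was lost with cyclic loess (adjusted p = 0.330, from 1.03e-04 to 0.330 over all alternatives). The higher members numbered 4 without in-sphere replicate 1 or 3 or outside replicate 3, and 3 without outside replicate 1. Gbp3 was the single interferon-stimulated call of 21 (1.36 ± 0.40, camera adjusted p = 0.249), and 0 were called adjusted over the list alone. That call was lost without in-sphere replicate 2 (adjusted p = 0.0560) or outside replicate 2 (adjusted p = 0.0759), the adjusted p running from 0.00362 to 0.170 over all alternatives. Alternative activation had 4 higher and 4 lower of 16 (4 and 4 adjusted over the list alone, camera adjusted p = 0.727), Clec7a differing by -2.27 ± 0.12 and Chil3 by -1.64 ± 0.24. Mrc1 was higher at 1.05 ± 0.28, adjusted p = 0.0108, a call lost without outside replicate 2 (adjusted p = 0.0512, from 0.00251 to 0.221 over all alternatives). The checkpoint ligand Cd274 was lower at -0.63 ± 0.16, adjusted p = 0.00980. Il10 differed by 0.50 ± 0.24, adjusted p = 0.121 and passed with the replicate block (adjusted p = 0.0209, from 0.0209 to 1.00 over all alternatives). Tnf (0.041 ± 0.14, adjusted p = 0.852) and Itgam (0.56 ± 0.25, adjusted p = 0.102) did not pass. The monocyte chemokine receptor Ccr2 was at 4.15 ± 0.46 and Cx3cr1 at 3.40 ± 0.21, in a list with 5 higher and 4 lower of 11 (5 and 5 adjusted over the list alone, camera adjusted p = 0.365).

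Lipid, antioxidant, lysosomal and engulfment genes were lower at 48 h. Of 16 genes of the LXR and lipid handling list 2 were higher and 14 lower (2 and 14 adjusted over the list alone). The median was -1.33 (camera adjusted p = 9.81e-06, adjusted p = 0.161 with an estimated correlation). Its members included Fabp4 at -3.07 ± 0.24, Pparg at -2.62 ± 0.19 and Nr1h3, which encodes LXR alpha, at -2.40 ± 0.22. Of 16 genes of the NRF2 list 0 were higher and 13 lower (0 and 13 adjusted over the list alone). The median was -0.90 (camera adjusted p = 9.81e-06, adjusted p = 0.209 with an estimated correlation). Its members included Osgin1 at -2.06 ± 0.17. Of 19 genes of the lysosome list 0 were higher and 15 lower (0 and 15 adjusted over the list alone). The median was -0.76 (camera adjusted p = 2.15e-07, adjusted p = 0.209 with an estimated correlation). Its members included Lipa at -1.84 ± 0.13. Of 17 genes of the engulfment of apoptotic cells list 1 was higher and 9 lower (1 and 9 adjusted over the list alone). The median was -0.37 (camera adjusted p = 0.00812, adjusted p = 0.212 with an estimated correlation). Its members included the integrin Itgb3 at -2.94 ± 0.32 and Gas6 at -1.78 ± 0.26, Itgb3 in spheres exceeding the filter level on 2 of 3 arrays. At 24 h 1 was higher and 7 lower in that list (1 and 7 adjusted over the list alone, camera adjusted p = 0.0553).

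Among markers of other cells, stromal genes had 9 higher and 3 lower of 15 (9 and 3 adjusted over the list alone, camera adjusted p = 0.00576, adjusted p = 0.523 with an estimated correlation), with Col3a1 at 3.28 ± 0.31. Granulocyte genes had 1 higher and 9 lower of 13 (2 and 9 adjusted over the list alone, camera adjusted p = 0.0104, adjusted p = 0.543 with an estimated correlation), with Ltf at -3.09 ± 0.32. Neural genes had 3 higher and 0 lower of 20 (3 and 0 adjusted over the list alone, camera adjusted p = 0.147). These were Gap43, Ncam1 and Elavl4. Elavl4 averaged 3.03 in spheres, close to the filter level, and exceeded that level outside on 0 of 3 arrays. Its 2 other probe sets were not called. Of 5 other probe sets of Ncam1, 4 were not called. Gap43 outside exceeded the filter level on 1 of 3 arrays. Macrophage identity genes had 2 higher and 7 lower of 20 (2 and 9 adjusted over the list alone, camera adjusted p = 0.140). The macrophage identity list passed with cyclic loess (adjusted p = 0.00595, from 0.00379 to 0.543 over all alternatives). In all, 10 lists were called higher and 5 lower at 48 h and the other lists did not pass. Median, mean and test differed in sign for tumour-associated macrophage effectors, MHC class II presentation, neuroblastoma and neural markers, endothelial markers and oxidative phosphorylation. Of the list calls 0 held with an estimated correlation, where the smallest adjusted p was 0.161.

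**Figure D2:**
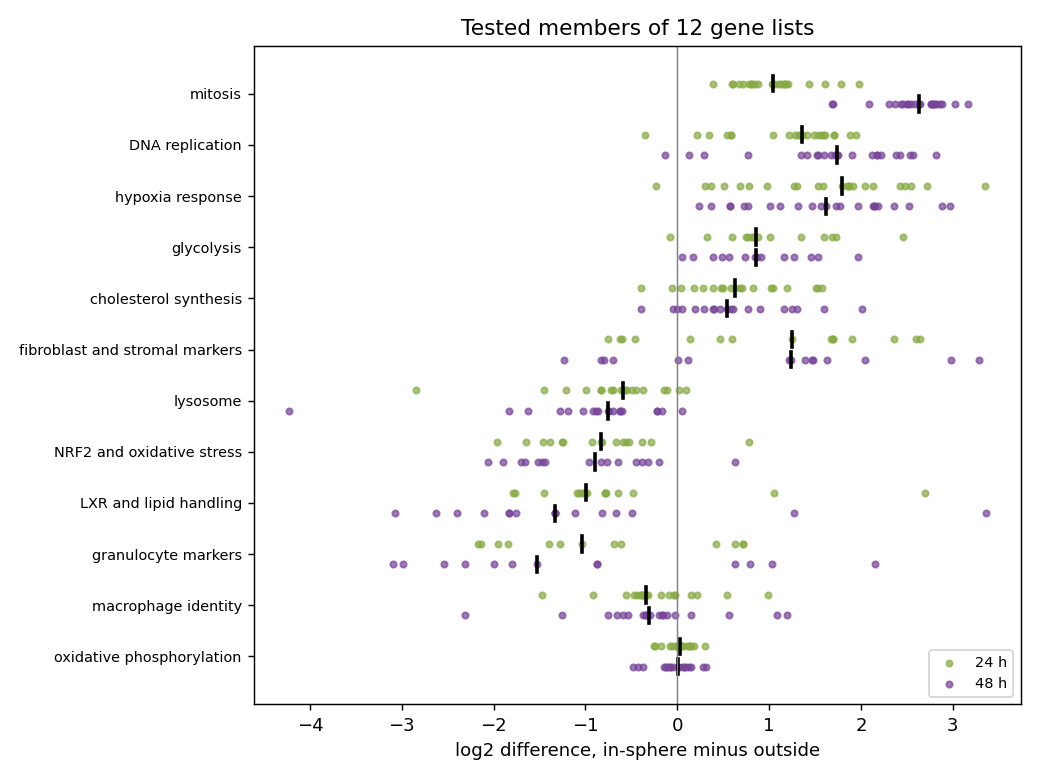
Log2 differences, in-sphere minus outside, of the tested members of 12 gene lists at 24 h and 48 h (points), with the median of each list as a black bar. Medians of the mitosis list lie at 1.04 and 2.64, and those of the lysosome list at -0.59 and -0.76.

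Genes that differed between the compartments at 24 h mostly did so at 48 h. The in-sphere differences at both times, which share no arrays, ran alike across genes (Pearson r = 0.870, genes not being independent replicates). Called at both times were 2801 genes. Of these, 1400 were higher in both against 301 for independent lists, 1398 were lower in both against 377, and 3 differed in opposite directions. The number for independent lists leaves out that the arrays of one replicate number are linked, outside arrays of the same number correlating at 0.471, 0.473 and 0.419 between the times after removal of group means, so part of the excess may come from these links. Averaged over both times, limma called 5774 genes, 2576 higher and 3198 lower. Which direction had more calls depended on scaling, since cyclic loess gave 3238 higher and 2773 lower. Without in-sphere 48 h replicate 3 the split was 2856 and 2890, without that array and in-sphere 24 h replicate 1 it was 2843 and 2807, and limma's treat gave 894 and 728. Of 23 hypoxia response genes 22 were higher and 0 lower (22 and 0 adjusted over the list alone, camera adjusted p = 1.43e-14, adjusted p = 0.225 with an estimated correlation). Of 23 mitosis genes 23 were higher and 0 lower (23 and 0 adjusted over the list alone, camera adjusted p = 5.33e-15, adjusted p = 0.255 with an estimated correlation), and of 19 lysosome genes 0 were higher and 15 lower (0 and 15 adjusted over the list alone, camera adjusted p = 2.20e-07, adjusted p = 0.232 with an estimated correlation). The list call of classical activation (camera adjusted p = 0.0371, adjusted p = 0.476 with an estimated correlation) was lost with cyclic loess (adjusted p = 0.0749, from 0.00222 to 0.476 over all alternatives), and macrophage identity (camera adjusted p = 0.0519) passed with it (adjusted p = 0.00798, from 7.60e-04 to 0.527 over all alternatives). Median, mean and test of this contrast differed in sign for tumour-associated macrophage effectors, MHC class II presentation, neuroblastoma and neural markers, immediate-early and heat-shock and oxidative phosphorylation.

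Between 24 h and 48 h in spheres no single gene passed in the fit without the replicate block. Values of list members that did not pass included the chemokine Cxcl11 (-1.54 ± 0.31), the granule proteins Camp (-1.54 ± 0.43) and Mpo (-1.49 ± 0.46), the collagen Col1a2 (1.37 ± 0.19, adjusted p = 0.0560), the quinone reductase Nqo1 (-1.26 ± 0.35) and the immediate-early factor Jun (0.80 ± 0.22). Limma called 0 genes, the smallest adjusted p being 0.0560, with 1341 at an unadjusted p under 0.05 against 624 by chance. With the replicate block it called 15, 4 higher and 11 lower, Col1a2 among them (adjusted p = 0.0253, from 0.0111 to 1.00 over all alternatives), and with array weights 115. Calls of 9 genes were made without replicate 2 at 24 h, and of 2 and 10 without replicates 1 and 2 at 48 h.

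Of the lists, camera called the immediate-early and heat-shock list upward in spheres from 24 h to 48 h, also with an estimated correlation, while 0 of its members passed over all genes. Its median was 0.25, with 0 members called over all genes, 8 higher and 0 lower at an unadjusted p under 0.05 and 6 and 0 adjusted over the list alone (camera adjusted p = 2.27e-06, adjusted p = 0.0311 with an estimated correlation). Upward shifts whose calls were lost with an estimated correlation were those of the next 4 lists. The mitosis median was 0.44, with 0 members called over all genes, 8 higher and 0 lower at an unadjusted p under 0.05 and 0 and 0 adjusted over the list alone (camera adjusted p = 1.38e-11, adjusted p = 0.791 with an estimated correlation). The lysosome median was 0.12, with 0 members called over all genes, 0 higher and 0 lower at an unadjusted p under 0.05 and 0 and 0 adjusted over the list alone (camera adjusted p = 0.00254, adjusted p = 0.791 with an estimated correlation), a call also lost with cyclic loess (adjusted p = 0.199, from 0.00245 to 0.791 over all alternatives). For DNA replication it was 0.067, with 0 members called over all genes, 2 higher and 0 lower at an unadjusted p under 0.05 and 1 and 0 adjusted over the list alone (camera adjusted p = 0.00319, adjusted p = 0.791 with an estimated correlation). For stromal genes it was 0.020, with 0 members called over all genes, 3 higher and 0 lower at an unadjusted p under 0.05 and 2 and 0 adjusted over the list alone (camera adjusted p = 0.0242, adjusted p = 0.791 with an estimated correlation), also lost with cyclic loess (adjusted p = 0.0962, from 0.0182 to 0.791 over all alternatives). Downward shifts were those of granulocyte genes, with a median of -0.92, with 0 members called over all genes, 0 higher and 9 lower at an unadjusted p under 0.05 and 0 and 9 adjusted over the list alone (camera adjusted p = 2.02e-06, adjusted p = 0.791 with an estimated correlation), and NRF2 genes, with a median of -0.29, with 0 members called over all genes, 0 higher and 6 lower at an unadjusted p under 0.05 and 0 and 4 adjusted over the list alone (camera adjusted p = 0.0130, adjusted p = 0.791 with an estimated correlation). Interferon-stimulated genes (median -0.46, 0 and 0 adjusted over the list alone, camera adjusted p = 0.0799) passed with the replicate block (adjusted p = 0.0310, from 0.0135 to 0.892 over all alternatives). LXR and lipid handling genes (median -0.18, camera adjusted p = 0.0946) passed with cyclic loess (adjusted p = 0.0195, from 0.0195 to 0.791 over all alternatives). Median, mean and test differed in sign in spheres over time for NF-kB feedback and early cytokines, tumour-associated macrophage effectors, MHC class II presentation, cholesterol synthesis, neuroblastoma and neural markers, dendritic cell markers, complement and apoptosis regulators and p53 targets.

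Outside spheres, few single genes passed between 24 h and 48 h in the fit without the replicate block. The interleukin Il6 (-2.84 ± 0.37), Hba-a1 (-2.66 ± 0.47), the transporter Slc13a3 (-2.65 ± 0.49), the granule protease Prtn3 (-2.22 ± 0.32) and the chemokine Cxcl10 (-2.15 ± 0.28) fell, and Mki67 fell with them (-1.56 ± 0.23, adjusted p = 0.0187). Slc13a3 was lower at 48 h in spheres too, averaging 6.30 at 24 h and 3.45 at 48 h, but did not pass there. Its in-sphere difference changed by -0.20 ± 0.69 between times (limma adjusted p = 0.934), so its fall was not particular to the outside cells. Ibsp (2.20 ± 0.28), Ptprz1 (1.76 ± 0.25), Lrrc27 (1.37 ± 0.18), the collagen Col1a1 (1.35 ± 0.21) and the histone gene H4bc24 (1.17 ± 0.17) rose, Ptprz1 exceeding the filter level at 24 h on 1 of 3 arrays. Limma called 42 genes, 14 higher and 28 lower, with 1352 at an unadjusted p under 0.05 against 624 by chance. With the replicate block it called 158, 60 higher and 98 lower, and with array weights 286. The 42 calls therefore do not show that few genes changed. The count was 13 without outside replicate 2 at 24 h, 0 without replicate 3 at 24 h, and 0 and 6 without replicates 1 and 3 at 48 h, so that all these calls were lost in at least 1 of these fits. It rose to 97 without the 2 least concordant in-sphere arrays.

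Inflammatory and cell division lists were called lower by camera outside spheres at 48 h, though few of their members passed and none of these list calls held with an estimated correlation. The mitosis median was -1.12, with 0 rising and 4 falling over all genes and 0 and 21 adjusted over the list alone (camera adjusted p = 5.98e-31, adjusted p = 0.163 with an estimated correlation). The 4 mitosis calls became 0 without outside replicate 2 or 3 at 24 h or replicate 1 or 3 at 48 h. For classical activation it was -0.47, with 0 rising and 2 falling over all genes and 0 and 5 adjusted over the list alone (camera adjusted p = 7.91e-09, adjusted p = 0.0751 with an estimated correlation). The NF-kB feedback median was -0.38, with 0 rising and 1 falling over all genes and 1 and 10 adjusted over the list alone (camera adjusted p = 8.79e-08, adjusted p = 0.258 with an estimated correlation). The DNA replication median was -0.31, with 0 rising and 1 falling over all genes and 1 and 3 adjusted over the list alone (camera adjusted p = 8.37e-08, adjusted p = 0.258 with an estimated correlation). For interferon-stimulated genes it was -0.63, with 0 members called over all genes, 0 higher and 2 lower at an unadjusted p under 0.05 and 0 and 0 adjusted over the list alone (camera adjusted p = 1.24e-04, adjusted p = 0.617 with an estimated correlation). The cytokine Il10 differed by -1.22 ± 0.24, adjusted p = 0.0651 and fell with the replicate block (adjusted p = 0.00574, from 0.00574 to 1.00 over all alternatives).

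Among the other lists outside spheres, the immediate-early median was -0.19, with 0 rising and 1 falling over all genes and 0 and 2 adjusted over the list alone (camera adjusted p = 1.46e-04, adjusted p = 0.0751 with an estimated correlation). The granulocyte median was -0.29, with 0 rising and 1 falling over all genes and 0 and 3 adjusted over the list alone (camera adjusted p = 1.46e-04, adjusted p = 0.445 with an estimated correlation). For MHC class II it was -0.36, with 0 members called over all genes, 0 higher and 3 lower at an unadjusted p under 0.05 and 0 and 0 adjusted over the list alone (camera adjusted p = 0.00107, adjusted p = 0.321 with an estimated correlation). The endothelial median was -0.32, with 0 members called over all genes, 0 higher and 1 lower at an unadjusted p under 0.05 and 0 and 1 adjusted over the list alone (camera adjusted p = 0.00418, adjusted p = 0.320 with an estimated correlation). The NRF2 median was -0.12, with 0 members called over all genes, 0 higher and 1 lower at an unadjusted p under 0.05 and 0 and 1 adjusted over the list alone (camera adjusted p = 0.0262, adjusted p = 0.606 with an estimated correlation), a call also lost with cyclic loess (adjusted p = 0.101, from 0.0110 to 0.606 over all alternatives). For neural genes it was -0.11, with 0 members called over all genes, 1 higher and 1 lower at an unadjusted p under 0.05 and 0 and 1 adjusted over the list alone (camera adjusted p = 0.0262, adjusted p = 0.258 with an estimated correlation), a call lost with cyclic loess (adjusted p = 0.0882) and with the replicate block (adjusted p = 0.0576, from 0.0170 to 0.258 over all alternatives). Lysosome, engulfment and lipid lists were called higher, again with no call that held with an estimated correlation. The lysosome median was 0.32, with 0 members called over all genes, 11 higher and 0 lower at an unadjusted p under 0.05 and 8 and 0 adjusted over the list alone (camera adjusted p = 2.50e-09, adjusted p = 0.203 with an estimated correlation). The engulfment median was 0.21, with 1 rising and 0 falling over all genes and 2 and 0 adjusted over the list alone (camera adjusted p = 0.00107, adjusted p = 0.203 with an estimated correlation). The LXR and lipid median was 0.17, with 0 members called over all genes, 3 higher and 0 lower at an unadjusted p under 0.05 and 2 and 0 adjusted over the list alone (camera adjusted p = 0.0214, adjusted p = 0.321 with an estimated correlation). Median, mean and test differed in sign outside spheres over time for unfolded protein and amino acid response, chemokine receptors and trafficking and oxidative phosphorylation.

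**Figure D3:**
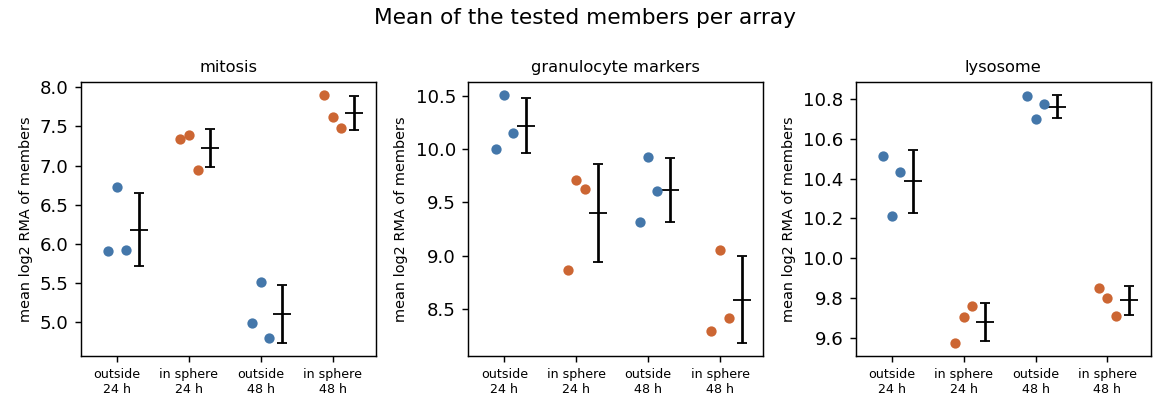
Mean log2 RMA value of the tested members of the mitosis, granulocyte and lysosome lists per array (points), with the mean and SD of the 3 arrays of each group. The mitosis mean outside spheres is 6.18 ± 0.47 at 24 h and 5.10 ± 0.37 at 48 h, against 7.22 ± 0.25 and 7.67 ± 0.21 in spheres.

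The change of the in-sphere difference between times passed for no gene in the fit without the replicate block. Among the named genes its largest positive values were those of Ccr2 (2.57 ± 0.65), the mitotic ubiquitin-conjugating enzyme Ube2c (2.21 ± 0.44), Cxcl10 (2.12 ± 0.40), Rrm2 (2.07 ± 0.48), Ccnb2 (2.00 ± 0.46) and Mki67 (2.00 ± 0.32, adjusted p = 0.107). Among the negative values were those of Dmp1 (-3.11 ± 0.91, adjusted p = 0.204), Ibsp (-2.11 ± 0.40, adjusted p = 0.107) and Mmp2 (-1.61 ± 0.38, adjusted p = 0.152). Ibsp in spheres exceeded the filter level on 0 of 3 arrays at both times. These 3 were named after their values had been seen. Limma called 0 genes, with 1534 at an unadjusted p under 0.05 against 624 by chance. With the replicate block it called 65, 45 with a growing and 20 with a falling difference, among them Ube2c, Cxcl10, Rrm2 and Mki67 (each adjusted p = 0.0375), Ccnb2 (adjusted p = 0.0440) and Ccr2 (adjusted p = 0.0421). Dmp1 (adjusted p = 0.0499, from 0.0499 to 1.00 over all alternatives) and Ibsp (adjusted p = 0.0288, from 0.0114 to 1.00) passed with it too. With array weights it called 130. Without outside 24 h replicate 2 or in-sphere 48 h replicate 2 it called 2. For the 6 genes of the positive values the adjusted p ran from 0.0298 to 1.00 over all alternatives.

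The immediate-early and heat-shock list was called upward for this change, also with an estimated correlation, while 0 of its members passed over all genes. Jun (1.25 ± 0.31) and Nr4a1 (1.03 ± 0.17) did not pass. Its median was 0.44, with 0 members called over all genes, 10 higher and 1 lower at an unadjusted p under 0.05 and 7 and 0 adjusted over the list alone (camera adjusted p = 1.90e-09, adjusted p = 0.00805 with an estimated correlation). Nr4a1 passed with the replicate block (adjusted p = 0.0421, from 0.0276 to 1.00 over all alternatives). The mitosis median was 1.61, with 0 members called over all genes, 21 higher and 0 lower at an unadjusted p under 0.05 and 21 and 0 adjusted over the list alone (camera adjusted p = 3.10e-35, adjusted p = 0.179 with an estimated correlation). The DNA replication median was 0.47, with 0 members called over all genes, 9 higher and 0 lower at an unadjusted p under 0.05 and 2 and 0 adjusted over the list alone (camera adjusted p = 1.90e-09, adjusted p = 0.362 with an estimated correlation). For classical activation it was 0.33, with 0 members called over all genes, 6 higher and 1 lower at an unadjusted p under 0.05 and 3 and 0 adjusted over the list alone (camera adjusted p = 1.76e-04, adjusted p = 0.313 with an estimated correlation). The NF-kB feedback median was 0.28, with 0 members called over all genes, 6 higher and 1 lower at an unadjusted p under 0.05 and 5 and 1 adjusted over the list alone (camera adjusted p = 3.37e-05, adjusted p = 0.511 with an estimated correlation). For MHC class II it was 0.057, with 0 members called over all genes, 4 higher and 0 lower at an unadjusted p under 0.05 and 1 and 0 adjusted over the list alone (camera adjusted p = 0.0229, adjusted p = 0.605 with an estimated correlation).

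Lists whose in-sphere difference moved downward between times were LXR and lipid handling, engulfment and lysosome. The LXR median was -0.36, with 0 members called over all genes, 0 higher and 8 lower at an unadjusted p under 0.05 and 0 and 7 adjusted over the list alone (camera adjusted p = 0.00533, adjusted p = 0.362 with an estimated correlation). The engulfment median was -0.29, with 0 members called over all genes, 0 higher and 4 lower at an unadjusted p under 0.05 and 0 and 4 adjusted over the list alone (camera adjusted p = 0.0312, adjusted p = 0.412 with an estimated correlation), a call also lost with the mean of probe sets (adjusted p = 0.0553, from 0.00974 to 0.412 over all alternatives). The lysosome median was -0.17, with 0 members called over all genes, 0 higher and 2 lower at an unadjusted p under 0.05 and 0 and 0 adjusted over the list alone (camera adjusted p = 0.0438, adjusted p = 0.767 with an estimated correlation). Median, mean and test of the change differed in sign for macrophage identity, alternative activation, interferon-stimulated, hypoxia response, cholesterol synthesis, fibroblast and stromal markers, complement and oxidative phosphorylation.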

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

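Tests of the neural markers, of the growth of the mitosis difference, of the share of all or of mature granulocytes, and of the count made with the replicate block were chosen only after the values they rest on had been seen. The change of the in-sphere difference from 24 h to 48 h was past the threshold of camera upward for 6 lists and downward for 3. Its median was 1.61 for mitosis, 0.47 for DNA replication, 0.44 for immediate-early and heat-shock genes, 0.33 for classical activation, 0.28 for NF-kB feedback and 0.057 for MHC class II, whose mean was 0.20. It was -0.36 for LXR and lipid handling, -0.29 for engulfment and -0.17 for lysosome genes. Of these calls, that of the immediate-early and heat-shock list held with an estimated correlation (adjusted p = 0.00805), and the smallest of the others was adjusted p = 0.179 for mitosis.

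Signals outside the gene comparisons also differed. A control probe set for the B1 repeat, a short interspersed element of mouse, was higher in spheres by 1.71 ± 0.18 at 24 h (SE, limma adjusted p = 7.32e-05) and 1.27 ± 0.18 at 48 h (adjusted p = 3.63e-04). The B2 repeat probe set of higher signal differed by -0.013 and 0.054. Among 9321 tested probe sets without a single gene name, limma called 1895 at 24 h, 2513 at 48 h, 3366 for the mean of both times, 21 for the change outside spheres and 3 for the change of the in-sphere difference.

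Some stromal and neural markers were higher in spheres, the 12 members of the stromal and neural lists called higher at either time. In the stromal list 2 members were called lower at 24 h and 3 at 48 h, and the neural list did not pass (camera adjusted p = 0.660 at 24 h and 0.147 at 48 h, median 0.010 at 24 h). Of the higher members, 10 averaged above the filter level of 2.77 outside spheres at 24 h and 0 stood in another list. Elavl4, at 3.03 in spheres at 48 h, lay close to that level. Col3a1 averaged 10.78 in spheres and 8.14 outside at 24 h, and Bgn 10.58 and 8.90. The array of lowest weight, in-sphere replicate 3 at 48 h, is not the source of the 48 h difference. Without it the members' median difference at 48 h was 1.04 times its value. That fit says nothing on the 24 h difference, which does not use this array. In-sphere replicate 1 at 24 h, with a weight of 0.347, had the highest stromal mean of its group (6.94 against 6.56 and 6.23). It was not left out in this test. No array of TT9423 cells alone was analysed here, so carried-over sphere cells were tested only through marker lists. Those with the neural markers cannot be told apart from none, as 2 of 20 markers were called higher at 24 h but their median level in spheres, 2.98, was close to the filter level. Carried-over cells of another profile may contribute, since across in-sphere arrays the members' mean correlation, 0.536, lay at percentile 99.8 of 10000 random lists matched on expression (median 0.160). Co-regulation within macrophages stays open, and the CD11b selection would remove such cells where it was complete.

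Mitosis genes were higher in spheres, more so at 48 h. The list's median change was -1.12 outside spheres against 0.44 in them. This argues against more dividing sphere cells carried over at 48 h as the whole source of that growth. They are not excluded, since the test was chosen after these values were seen. The list call outside spheres also did not hold with an estimated correlation. Median centring and cyclic loess left the 48 h difference in place, the lowest share kept being 1.01. RMA had already quantile-normalised the arrays, so these scalings do not test that earlier step, and its effect is not excluded. Dividing sphere cells carried over at both times stay open: mitosis and stromal deviations over 6 in-sphere arrays gave a Pearson r of 0.603 (exact permutation p = 0.215) and a Spearman rho of 0.486 (exact permutation p = 0.356), with r = 0.225 without the 2 farthest arrays. A difference in division between macrophages in and outside spheres may also contribute and is untested.

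Granulocyte markers were lower in spheres, S100a8 averaging 12.26 in spheres and 13.14 outside at 48 h and S100a9 12.71 and 13.58. A lower share of all granulocytic cells, precursors included, would lower the 4 primary granule genes too. Their median difference was 0.92 at 48 h, with 1 called higher, which argues against it for these genes. Such a share is not excluded, since the arrays do not show which cells carry these transcripts. Median centring and cyclic loess left the 48 h difference in place, the lowest share kept being 0.984. An effect of the earlier scaling within RMA is not excluded. All 9 other members were called lower at both times. That is the pattern itself, so it cannot test whether a lower share of mature granulocytes accounts for it. Mature granulocytes also carry CD11b and so would pass the CD11b selection of the in-sphere cells. Whether cells from outside were selected in the same way is not given. Of the 9 other members, 9 averaged above the filter level in spheres at 48 h and 2 stood in another list. A lower share of mature granulocytes and lower expression within macrophages both stay open.

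Other splits of the arrays bear on the counts of called genes. With 10 splits of 6 arrays, the splits are too few for a share under 0.05. The real counts were 3669 at 24 h, 4685 at 48 h and 42 outside over time, and the highest others 0, 0 and 1. Among the other splits parting all 3 numbered pairs the highest count was 0 in each. In spheres over time the real count was 0, which any split reaches, so the splits test nothing there. For the mean of both times, 1 of 100 drawn splits gave as many as the real 5774. Chance can be excluded there. The highest other count, 2261, came from the 14 splits that kept the real groups at one time, and the rest gave 0. For the change of the in-sphere difference the real count was also 0, which all 100 permutations of residuals reach by construction, so they test nothing either. With the replicate block, residuals were permuted among the arrays of a replicate number, and 2 of 100 such permutations, the real one included, gave as many as the real 65. That share is under 0.05, but the count was chosen for this test after it had been seen, so chance is not excluded. The highest other, 567, came from the 1 permutation that kept the contrast of the real grouping or its mirror, the rest gave at most 3, and 94 others gave 0.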

How the results depend on the processing

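Leaving out the 2 least concordant arrays was chosen after seeing the data. Counts of called genes for in-sphere against outside stayed within 1.5 times the reported ones under every alternative except limma's treat, which tests against a larger difference. Treat called 966 at 24 h, 1389 at 48 h and 1622 for the mean of both times, and 0 outside spheres over time. Without 1 array they ran from 2930 to 3584 at 24 h, 3811 to 4390 at 48 h and 5195 to 5746 for the mean. In spheres over time they ran from 0 to 10, outside from 0 to 41 and for the change of the difference from 0 to 2. For spheres over time, outside over time and the change of the difference, counts were 15, 158 and 65 with the fixed replicate block and 9, 111 and 7 with cyclic loess. They were 11, 89 and 7 with the trended robust fit, and 115, 286 and 130 with array weights. In spheres over time they were 3 with the mean of probe sets, 4 with no filter, 4 with the stricter filter and 13 with median centring. The mean of probe sets gave 1 for the change of the difference. Outside over time the fit to the compared groups alone, with fewer degrees of freedom, called 1, and leaving out the 2 least concordant arrays gave 97. Apart from treat and fits with fewer arrays, the cause was not tested. Beyond the calls given with the report's results, the replicate block made calls of Mgl2, Fabp4, Npy, Cd79b, Nqo1, Atp6v0d2 and Ccr2 outside over time, Npy, Prtn3, Mfge8 and Il10 for the change of the difference, and changed no other call of a list, or of a gene in a comparison for which it was named. Of genes named for other comparisons, it also called Cenpe, Ccna2, Nusap1 and Kif20a for the change of the difference, and their other comparisons were not searched. No filter or the mean of probe sets made list calls of endothelial markers, engulfment of apoptotic cells, mast cell and basophil markers and NF-kB feedback and early cytokines at 24 h, macrophage identity at 48 h, macrophage identity for the mean of both times, interferon-stimulated and LXR and lipid handling in spheres over time, fibroblast and stromal markers outside over time, neuroblastoma and neural markers and endothelial markers for the change of the difference. Of 245 called values of named genes, 40 lost the call when 1 array was left out. Called values turned in sign only in probe sets not used, none of them called. Their values were at 24 h Slc7a2 -0.11, Pfkl -0.075 and Fscn1 -0.11 and at 48 h Pfkl -0.49, Cd80 -0.24, Ncam1 -0.023, Erg 0.043, Fscn1 -0.15, Cd4 0.023 and Sdha 0.12. Of named called genes with other probe sets, 29 of 67 at 24 h and 30 of 75 at 48 h had one not called. By fry, 17, 18, 24, 1, 5 and 3 lists passed in the 6 comparisons, in the order of the report. Signal over background limits genes below the filter level of 2.77, whose differences RMA compresses.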

Other observations

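The 6 gene lists of this part were written only after the top genes had been seen, and the genes named from them were chosen after their values were seen. Some members were then known to differ, so the tests describe these data and are no independent evidence. Of their members, 4 of 21 (osteoclast genes), 4 of 16 (blood monocyte genes), 1 of 19 (TFEB and TFE3 targets), 3 of 14 (iron and red-pulp macrophage genes), 8 of 22 (collagens and basement membrane) and 6 of 16 (serine and one-carbon synthesis) also stand in the lists fixed earlier. Genes of collagens and basement membrane were higher in spheres, where 14 of 21 were higher and 1 lower at 24 h (camera adjusted p = 1.32e-10, adjusted p = 0.0684 with an estimated correlation), and 15 of 21 were higher and 1 lower at 48 h (camera adjusted p = 1.85e-09, adjusted p = 0.0730 with an estimated correlation). The basement membrane genes Col4a1 and Lamb1 differed by 2.89 ± 0.24 and 2.91 ± 0.25 at 48 h, and the microfibril gene Fbn2 by 3.77 ± 0.27. Of serine and one-carbon synthesis genes, 10 of 13 were higher and 0 lower at 24 h (camera adjusted p = 2.15e-07, adjusted p = 0.0384 with an estimated correlation), and 10 of 13 were higher and 0 lower at 48 h (camera adjusted p = 2.25e-07, adjusted p = 0.0431 with an estimated correlation), with the mitochondrial folate enzyme Mthfd1l at 2.81 ± 0.21. Of blood monocyte genes, 5 of 13 were higher and 4 lower at 24 h (camera adjusted p = 0.265), and 8 of 13 were higher and 3 lower at 48 h (camera adjusted p = 0.00117, adjusted p = 0.0763 with an estimated correlation), with the coagulation factor F13a1 at 3.29 ± 0.21 and the proteoglycan Vcan at 3.25 ± 0.42.

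Genes of iron handling and red-pulp macrophages were lower in spheres, where 0 of 13 were higher and 9 lower at 24 h (camera adjusted p = 2.09e-06, adjusted p = 0.0384 with an estimated correlation), and 0 of 13 were higher and 10 lower at 48 h (camera adjusted p = 1.16e-05, adjusted p = 0.0431 with an estimated correlation). At 48 h the iron exporter Slc40a1 differed by -3.78 ± 0.20, the transcription factor Spic by -3.02 ± 0.32, the secreted protein Cd5l by -3.86 ± 0.42 and the transferrin receptor Tfrc by -2.02 ± 0.13. Of TFEB and TFE3 targets, which serve lysosomes and autophagy, 1 of 16 was higher and 12 lower at 24 h (camera adjusted p = 1.37e-05, adjusted p = 0.0684 with an estimated correlation), and 1 of 16 was higher and 12 lower at 48 h (camera adjusted p = 1.16e-05, adjusted p = 0.0730 with an estimated correlation). Of osteoclast genes, 1 of 17 was higher and 7 lower at 24 h (camera adjusted p = 1.68e-04, adjusted p = 0.0684 with an estimated correlation), and 0 of 17 were higher and 12 lower at 48 h (camera adjusted p = 1.07e-05, adjusted p = 0.0581 with an estimated correlation). That list also holds Ibsp and Dmp1, which are known from bone matrix and had the largest differences toward the outside cells at 48 h. Its median was -0.71 at 24 h and -0.94 at 48 h.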
